A study of Mus musculus with 37 samples.

How the data were processed

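RNA-seq libraries from mouse bone-marrow-derived macrophages were used: 2 genotypes (WT and Arid1a KO), 3 time points (days 0, 2 and 4 of culture toward osteoclasts) and 2 libraries per group, 12 of the 37 samples of the series. The other samples, 12 ATAC-seq and 13 CUT&Tag libraries, were not analysed here. Groups, days and replicate numbers were taken from the labels. The free-text description of the design names osteoblasts where the title and labels name osteoclasts; the labels were followed.

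The deposited count table gives expected counts per gene, whole numbers with sums per library from about 16282200 to 18608400. The deposited TPM table gives TPM (transcript abundance scaled to a common total) as the authors computed it; the listed genes sum to 984 to 989 in units of 1e3 per library. Per the submitters' processing notes, the tools were Trim Galore 0.6.1, STAR 2.7.3a, RSEM 1.3.1 and DESeq2, without a stated role or order, and the builds mm9 and mm10 are both named without saying which assay used which. The gene models and the strand setting are not stated. RSEM shares reads between similar genes, so H2-Q7 and H2-Q9, and Il4i1 and Il4i1b, which hold identical values, were not named. Of the gene names, 26 had turned into dates. Of these 17 were tested; they held at most 0.216% of a library's counts and are counted but not named. Names matched the RefSeq gene table of GRCm38.p6 for 21715 of 23170 genes (93.7%), which was used only for names and for which genes neighbour each other.

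All 12 libraries were fitted together with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with its minimum count of 10, 1 mean per group, robust quasi-likelihood dispersions and the quasi-likelihood F test, two-sided. The filter left 12774 genes. The common biological coefficient of variation was 0.261 and the median prior degrees of freedom 2.66. The Benjamini-Hochberg method adjusted p over the genes of a comparison, and an adjusted p under 0.05 was a call. The SE of a log2 fold change was its size divided by the square root of F. The 9 comparisons were KO against WT at each day, each later day against day 0 within each genotype, and the change of the KO effect from day 0 to day 2 and to day 4 (the interaction). CPM used TMM-scaled library sizes. A group at 0 counts was set at a floor of 3 counts over the group, and a group with 1 to 3 counts was given as a ratio with an exact 95% counting interval. Calls shared by comparisons without a common library were tested with Fisher's exact test, two-sided, adjusted over the 20 pairs of directions. All comparisons came from the same fit, so each gene's estimated spread was shared between them.

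The comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined, except where stated otherwise. The rule named Arid1a, Siglec15, Jun and Fos in every KO against WT comparison. It added the 8 largest rises and 8 largest falls for each day (adjusted p under 0.05, mean of at least 5 CPM over the 12 libraries, KO libraries on one side of the WT libraries). For WT time comparisons and interactions it added 5 of each. It also added up to 4 members with the smallest adjusted p from each list that passed, and in any case from the osteoclast, RANK signalling, AP-1, BAF and anti-osteoclastogenic lists. Predicted genes and pseudogenes were counted but not named. The text leaves out many of these names.

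The 31 fixed gene lists were osteoclast, RANK signalling, AP-1 family, BAF subunits, anti-osteoclastogenic genes (those that restrain osteoclast formation), antigen presentation, cell cycle, cell fusion, cholesterol synthesis, cytoskeleton and podosome, endoplasmic reticulum stress, glycolysis, inflammatory, interferon, lysosome, macrophage, matrix adhesion, oxidative phosphorylation, p53 targets, V-ATPase, RNAs of the mitochondrial genome as an RNA-quality check, a check of sex-linked genes, and markers of B cells, dendritic cells, erythroid cells, stromal cells, mast cells and basophils, megakaryocytes, neutrophils, osteoblasts, and T and NK cells. Each was tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data, with fry and with replicate blocks. With a preset correlation many lists passed; with an estimated correlation only the lists named in the text as holding did.

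Alternatives were a log2 fold change of at least 1, DESeq2 size factors in edgeR, no low-count filter, a stricter filter (5 CPM in 2 libraries), the DESeq2 1.42.0 Wald test, limma-voom, limma on log2(TPM + 1), the libraries of a comparison fitted alone, replicate numbers as a block, and each library left out in turn. With 1 library left out, the lone library of its group was assumed to vary like the other groups. The log2 differences between replicates 1 and 2 correlated across genes between days within WT (r = 0.17, 0.11 and 0.27) and within KO (0.53, 0.39 and 0.43), and between genotypes from -0.48 to 0.043. A block by number within each genotype, chosen before the data were examined, was an alternative for the time and interaction comparisons.

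The test was checked on simulated counts with the dispersions of the data, for 12774 genes per comparison, of which 100 were changed by 2-fold and 100 by 4-fold. These genes had a mean of at least 5 CPM and lay outside the fixed lists, and a small planted list was also changed by 2-fold. Libraries were drawn independently, while replicate differences in the data correlated between groups. The shares below therefore describe independent libraries only. For KO against WT at day 0, 36% of the 2-fold and 81% of the 4-fold changes were called, and 3.05% of calls were false; at day 2 the values were 35%, 85% and 3.70%, and at day 4 they were 38%, 86% and 4.35%. For WT day 2 against day 0 they were 38%, 90% and 8.84%. For the interaction at day 2, 5% of the 2-fold and 70% of the 4-fold changes were called, and at day 4 they were 5% and 73%.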

Results

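RNA was sequenced from cultures of mouse bone-marrow-derived macrophages, wild type (WT) or knockout (KO) for Arid1a, at day 0 and after 2 or 4 days of culture toward osteoclasts, the multinucleated cells that resorb bone. Arid1a encodes a DNA-binding subunit of the BAF chromatin-remodelling complex. The 6 groups held 2 libraries each, 12 in all, with total counts from about 16282200 to 18608400. Of 23170 listed genes, 12774 had enough counts to be tested. Nothing in the labels says whether the 2 replicates of a group were separate cultures or animals, so p-values may measure technical spread. Levels are in CPM (counts scaled to library size), as mean ± SD with n = 2 unless stated; log2 fold changes are given ± SE; "called" means an adjusted p under 0.05 in the edgeR quasi-likelihood test. In each gene named as higher or lower in KO than in WT, both KO libraries of that day lay on the same side of both WT libraries. Intervals and bounds from low counts cover counting error only.

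Arid1a was lower in KO than in WT at each day, and its counts did not disappear. At day 0 the 2 WT libraries held 242 and 197 CPM and the 2 KO libraries 94.6 and 104 CPM. At day 2 the levels were 169 and 175 CPM in WT against 118 and 117 CPM in KO, and at day 4 they were 164 and 135 CPM in WT against 84.7 and 98.0 CPM in KO. The log2 fold change was -1.15 ± 0.14 at day 0 (adjusted p = 0.0141), -0.54 ± 0.14 at day 2 (adjusted p = 0.0613, not called) and -0.71 ± 0.14 at day 4 (adjusted p = 0.00793). Both KO libraries lay below both WT libraries at every day. Counts summed over a whole gene cannot show whether an exon was deleted. The day 0 call was lost without WT replicate 1 (adjusted p = 0.0526), KO replicate 1 (0.0995) or KO replicate 2 (0.105), and the day 4 call without WT replicate 1 (0.0585). With the 4 libraries of a day fitted alone, it was called at day 2 (adjusted p = 0.0332) and not at day 0 (0.0710) or day 4 (0.0966).

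Siglec15, the receptor gene that the series title names, rose in WT and stayed far lower in KO, without passing the threshold between genotypes. WT held 0 CPM at day 0, 1.74 ± 0.68 CPM at day 2 and 18.8 ± 1.84 CPM at day 4. KO held 0 counts at day 2, so WT was at least 17.8-fold higher there over a floor of 3 counts per group (adjusted p = 0.0990). At day 4 the KO libraries held 5.38 and 0.388 CPM (log2 fold change -2.70 ± 1.05, adjusted p = 0.110). At day 0 both groups were below the floor. Without KO day 4 replicate 1 the day 4 difference was called (log2 fold change -5.57, adjusted p = 0.00309), and DESeq2 called it at day 2 (adjusted p = 0.00192) and day 4 (0.0484). The change of the KO effect from day 0 was not called for Siglec15 at day 2 (adjusted p = 0.568) or day 4 (0.496), nor for Arid1a (0.481 and 0.196).

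**Figure D1:**
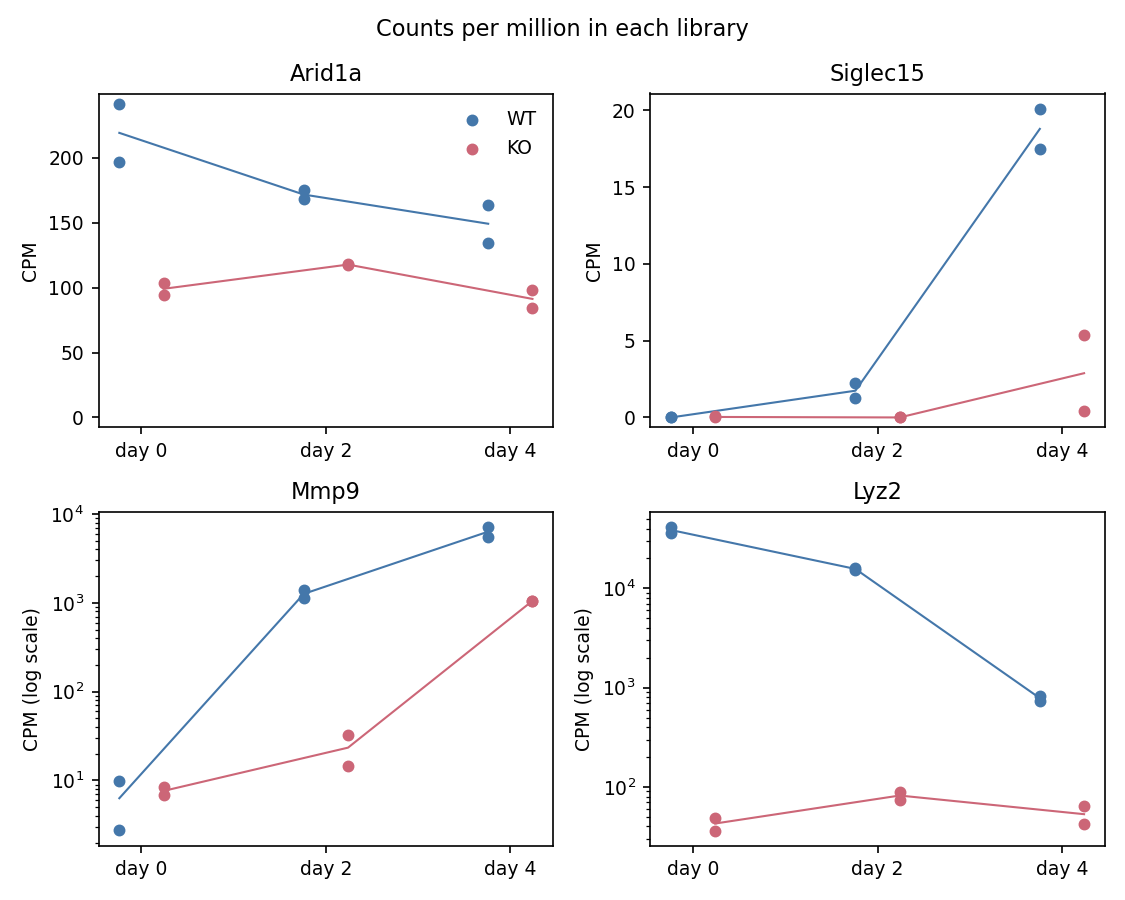
CPM of Arid1a, Siglec15, Mmp9 and Lyz2 in each library at days 0, 2 and 4 (points; lines join the means of n = 2; blue WT, red KO; Mmp9 and Lyz2 on a log axis). Mean Mmp9 reached 6334 CPM in WT and 1054 CPM in KO at day 4. Mean Lyz2 fell from 38669 to 784 CPM in WT, while the KO group means lay between 42.8 and 82.0 CPM.

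The day 4 libraries separated from the others. The first principal component held 48.8% of the variance and set the day 4 libraries (67.0 to 125) apart from the others (-63.5 to -30.7). On the second component (20.7%) the KO libraries lay above the WT libraries of the same day at days 2 and 4. At day 0 the genotypes overlapped (WT at 48.0 and -7.15, KO at 0.73 and 33.4). The 2 KO day 4 libraries lay far apart on it, at 19.6 and 103. Of the 12774 genes tested, 1237 differed by over 2-fold between these 2 libraries, with a small constant added to each CPM. The same count was 127 between the WT day 4 libraries and 1139 between the WT day 0 libraries.

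**Figure D2:**
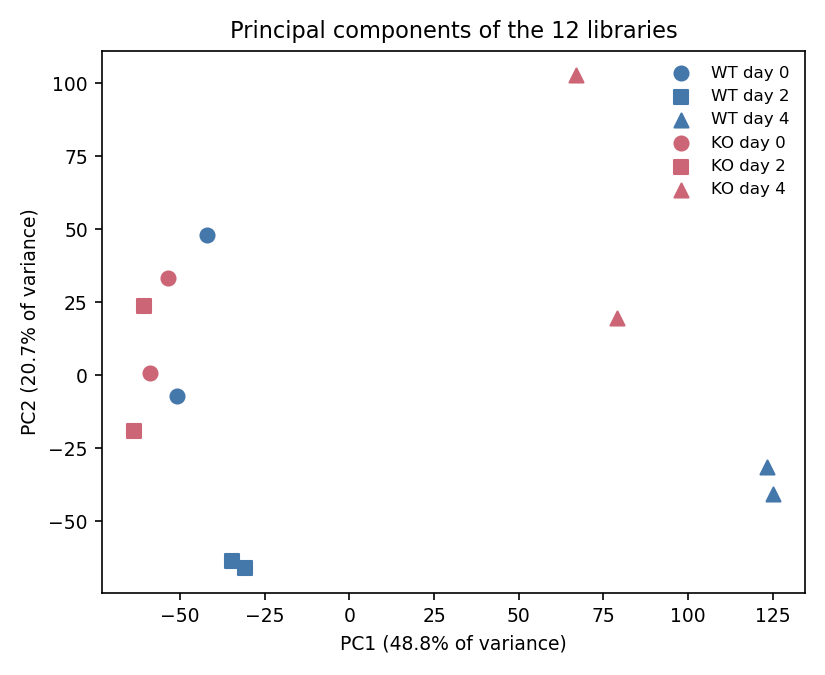
The first 2 principal components of log2 CPM for the 12 libraries (one point each; color gives genotype, shape gives day). Day 4 libraries lie at the right, with the 2 KO day 4 libraries at 19.6 and 103 on the second component.

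The WT time course gave the background of normal differentiation. By day 2 the osteoclast protease gene Mmp9 rose from 6.31 ± 5.06 to 1262 ± 196 CPM (log2 fold change 7.64 ± 0.69, adjusted p = 0.000949), and the AP-1 transcription factor gene Fosb rose from 0.566 ± 0.059 to 242 ± 48 CPM (8.72 ± 0.30, adjusted p = 7.59e-06). Ocstamp, needed for cell fusion, went from 1 count to 941 counts over the group, a ratio of 991 (95% interval 172 to 37914). Of 22 osteoclast genes measured, 10 rose and 1 fell (12 and 1 adjusted over the list alone, median log2 fold change 2.35, or 2.23 with genes at 0 counts set at their bound), and the list passed camera but not with correlations estimated from the data (adjusted p = 0.30 with an estimated correlation). Of 16 AP-1 family genes 12 rose and 0 fell (12 and 1 adjusted over the list alone, median 2.76), among them Junb (3.47 ± 0.17) and Jun (3.75 ± 0.32), and this list also passed with an estimated correlation (adjusted p = 0.016).

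Some energy, stress and inflammatory genes also rose at day 2, though no list in this paragraph held with an estimated correlation. Of 17 glycolysis genes 15 rose and 0 fell (17 and 0 adjusted over the list alone, median 1.38), such as the lactate transporter gene Slc16a3 (2.63 ± 0.20). Of 27 inflammatory genes 16 rose and 0 fell (20 and 2 adjusted over the list alone, median 2.20, or 2.14 with bounds), led by the chemokine gene Ccl2, which went from 4.06 ± 0.89 to 163 ± 30 CPM (5.32 ± 0.24). Rises were called for 10 of 18 endoplasmic reticulum stress genes with 0 falls (10 and 0 adjusted over the list alone, median 0.97). Of 20 cell fusion genes 6 rose and 2 fell (11 and 2 adjusted over the list alone, median 0.82), and of 16 genes that restrain osteoclast formation 5 rose and 0 fell (7 and 2 adjusted over the list alone, median 0.59), among them Id2 (3.28 ± 0.14). Each of these 5 lists lost its call narrowly (adjusted p = 0.051 with an estimated correlation). Oxidative phosphorylation genes rose in 8 of 33 cases with 0 falls (12 and 0 adjusted over the list alone, median 0.31, adjusted p = 0.65 with an estimated correlation), such as Cycs (1.51 ± 0.19).

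Macrophage genes fell at day 2 in WT in 7 of 26 cases and rose in 2 (11 and 2 adjusted over the list alone, median -0.79, adjusted p = 0.56 with an estimated correlation), among them Csf1r, which encodes the receptor for macrophage colony-stimulating factor (-0.94 ± 0.13). Matrix adhesion genes rose in 5 of 25 cases and fell in 1 (5 and 1 adjusted over the list alone, median 1.62, adjusted p = 0.56 with an estimated correlation), and podosome and cytoskeleton genes rose in 6 of 22 and fell in 2 (7 and 4 adjusted over the list alone, median 0.49, adjusted p = 0.17 with an estimated correlation). Of 21 cholesterol synthesis genes 2 rose and 4 fell (2 and 8 adjusted over the list alone, median -0.46, adjusted p = 0.65 with an estimated correlation). None of 26 interferon genes was called by edgeR or over the list alone (median -0.69, adjusted p = 0.72 with an estimated correlation). Markers of stromal cells rose beside these groups in 2 of 16 cases, with 0 falls (2 and 0 adjusted over the list alone, median 1.89, adjusted p = 0.67 with an estimated correlation). In all, 1029 genes rose and 1182 fell. On the TPM scale the split was 1247 higher and 648 lower, and the median of all genes was shifted by 0.10 in log2. The total of 2211 went to 1238 without WT day 0 replicate 1, 1461 without WT day 0 replicate 2, 488 without WT day 2 replicate 1 and 538 without WT day 2 replicate 2.

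By day 4, 7255 of the 12774 genes tested were called in WT against day 0, and 4522 at a log2 fold change of at least 1. Mmp9 reached 6334 ± 1101 CPM (9.97 ± 0.76, adjusted p = 2.6e-05), and Tnfrsf11a, which encodes the receptor RANK, rose from 42.8 ± 7.6 to 204 ± 7.5 CPM (2.26 ± 0.13, adjusted p = 6.4e-06). Csf1r fell from 7203 ± 251 to 918 ± 83 CPM (-2.97 ± 0.14). Osteoclast genes rose in 19 of 22 cases with 0 falls (19 and 0 adjusted over the list alone, median 4.38, adjusted p = 0.31 with an estimated correlation). Macrophage genes fell in 24 of 26 cases with 0 rises (25 and 0 adjusted over the list alone, median -5.05, adjusted p = 0.18 with an estimated correlation). Oxidative phosphorylation genes rose in 32 of 33 cases with 0 falls (32 and 0 adjusted over the list alone, median 1.52), such as Cs, which encodes citrate synthase (2.14 ± 0.15). Rises were called for 14 of 18 genes of the V-ATPase, the proton pump that acidifies the resorption space, with 1 fall (15 and 1 adjusted over the list alone, median 1.17). These 2 lists gave adjusted p = 0.31 with an estimated correlation.

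Other gene groups also moved in WT by day 4. Against day 0, the AP-1 median was 0.06 at day 4 (0.30 on the TPM scale), after 2.76 at day 2. The inflammatory median was -1.08 at day 4 (-0.35 on the TPM scale), after 2.20 at day 2. Cell cycle genes rose in 25 of 31 cases with 0 falls (30 and 0 adjusted over the list alone, median 2.25, adjusted p = 0.48 with an estimated correlation), such as Mcm6 (2.99 ± 0.28). Rises were called for 16 of 21 cholesterol synthesis genes with 1 fall (16 and 1 adjusted over the list alone, median 1.15), 14 of 18 endoplasmic reticulum stress genes with 1 fall (14 and 1, median 1.07) and 14 of 17 glycolysis genes with 1 fall (14 and 1, median 1.27). Falls were called for 19 of 26 lysosome genes with 1 rise (19 and 1 adjusted over the list alone, median -0.85) and 10 of 16 genes that restrain osteoclast formation with 1 rise (10 and 1, median -1.44). All 5 gave adjusted p = 0.31 with an estimated correlation. Antigen presentation genes fell in 13 of 17 cases with 0 rises (13 and 0 adjusted over the list alone, median -1.74, adjusted p = 0.49 with an estimated correlation). Neutrophil markers fell in 2 of 4 cases with 0 rises (2 and 0 adjusted over the list alone, median -4.86, adjusted p = 0.31 with an estimated correlation). In all, 3723 genes rose and 3532 fell, and the count stayed between 5877 and 6688 with any 1 of the 4 libraries left out. On the TPM scale the split was 4212 higher and 2817 lower, and the median of all genes was shifted by 0.14 in log2.

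The KO time course gave the changes that occurred with Arid1a lowered. Fosb rose from 0.463 ± 0.017 to 281 ± 30 CPM by day 2 (9.22 ± 0.31, adjusted p = 6.2e-06), and Fos rose from 5.46 ± 1.08 to 1031 ± 158 CPM (7.56 ± 0.65, adjusted p = 0.00069). Mmp9 moved from 7.63 ± 1.14 to 23.4 ± 12.8 CPM and was not called (1.62 ± 0.55, adjusted p = 0.15), although DESeq2 called it (adjusted p = 0.012). AP-1 genes rose in 9 of 16 cases with 0 falls (12 and 0 adjusted over the list alone, median 1.92), inflammatory genes in 16 of 27 with 0 falls (22 and 0, median 2.97), and genes that restrain osteoclast formation in 6 of 16 with 0 falls (6 and 0, median 0.29). These 3 lists held (adjusted p = 0.0055 with an estimated correlation). Only 1 of 22 osteoclast genes rose and 0 fell (2 and 0 adjusted over the list alone, median 0.01 in log2, which turned to -0.04 on the TPM scale), and the list was not called. Glycolysis genes rose in 3 of 17 cases with 0 falls (13 and 0 adjusted over the list alone, median 0.59, adjusted p = 0.19 with an estimated correlation), endoplasmic reticulum stress genes in 4 of 18 with 0 falls (5 and 0, median 0.20, adjusted p = 0.26 with an estimated correlation), RANK signalling genes in 5 of 29 with 1 fall (9 and 1, median 0.15, adjusted p = 0.47 with an estimated correlation) and antigen presentation genes in 1 of 17 with 0 falls (2 and 0, median 0.51, adjusted p = 0.61 with an estimated correlation). Cholesterol synthesis genes fell in 6 of 21 cases with 0 rises (13 and 1 adjusted over the list alone, median -0.56, adjusted p = 0.28 with an estimated correlation). None of 31 cell cycle genes (median -1.19, adjusted p = 0.63 with an estimated correlation) or 26 interferon genes (median 0.53, adjusted p = 0.87 with an estimated correlation) was called by edgeR, over all genes or over the list alone. In all 385 genes rose and 221 fell. That total of 606 went to 131 without KO day 0 replicate 1, 121 without KO day 0 replicate 2, 239 without KO day 2 replicate 1 and 150 without KO day 2 replicate 2.

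By day 4 the KO cultures had also moved, with 2977 genes higher and 2724 lower than at day 0. Against day 0, the AP-1 median was 0.05 at day 4, after 1.92 at day 2. The inflammatory median was 1.02 at day 4, after 2.97 at day 2. Mmp9 reached 1054 ± 0.36 CPM (7.11 ± 0.68, adjusted p = 0.00016), and Tnfrsf11a reached 217 ± 9.3 CPM (2.07 ± 0.13, adjusted p = 2.6e-05). Acp5, which encodes the osteoclast acid phosphatase TRAP, held 1135 and 298 CPM in the 2 KO libraries (5.03 ± 0.76, adjusted p = 0.0012). Osteoclast genes rose in 13 of 22 cases with 0 falls (14 and 1 adjusted over the list alone, median 1.84), cell cycle genes in 25 of 31 with 0 falls (31 and 0, median 2.21) and oxidative phosphorylation genes in 30 of 33 with 0 falls (30 and 0, median 0.82). Macrophage genes fell in 16 of 26 cases and rose in 3 (17 and 3 adjusted over the list alone, median -1.53), and lysosome genes fell in 17 of 26 and rose in 1 (17 and 1, median -0.76). These 5 lists gave adjusted p = 0.63 with an estimated correlation. Interferon genes, which were not called as a group in WT, rose in 14 of 26 cases with 0 falls (17 and 0 adjusted over the list alone, median 1.94, adjusted p = 0.80 with an estimated correlation). Markers of stromal cells were called in 0 of 16 cases (0 adjusted over the list alone, median -2.35, or -2.94 on the TPM scale). Matrix adhesion genes rose in 4 of 25 and fell in 6 (4 and 6 adjusted over the list alone, median -1.74). Neither list passed. On the TPM scale the split of all calls was 3281 higher and 2170 lower, and the median of all genes was shifted by 0.11 in log2. Without KO day 0 replicate 2 the total of 5701 went to 3860, and no library moved it further.

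Genes called in both the WT and the KO time course mostly moved in the same direction. By day 4, 2451 genes rose in both against 868 that would be shared if the calls were independent, 2182 fell in both against 753, and 37 and 41 moved in opposite directions. By day 2, 278 genes rose in both against 31.0 (Fisher's exact test, adjusted p = 2.85e-226) and 184 fell in both against 20.4 (adjusted p = 1.81e-155). WT had 1029 rises and 1182 falls at day 2, and most of these were not called in KO. That alone does not show a difference between genotypes, and the day 2 interaction called 1 of 12774 genes. On simulated counts, 44% of 2-fold changes were called for KO day 2 against day 0, and 5% for that interaction. The Fisher's exact tests treat genes as independent and leave out that the comparisons share each gene's estimated spread.

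At day 0, before differentiation, 202 genes were called between KO and WT macrophages, and Lyz2 had the largest fall. Lyz2, which encodes the macrophage lysozyme, held 38669 ± 3748 CPM in WT and 42.8 ± 9.1 CPM in KO (log2 fold change -9.82 ± 0.33, adjusted p = 7.4e-06). It was the gene with the highest count in both WT day 0 libraries, at 3.82% and 3.50% of all counts. Hal, which encodes a histidine-degrading enzyme, held 676 counts in WT and 1 count in KO, a ratio of 603 (95% interval 111 to 24536). The interleukin gene Il1b was higher (37.1 ± 14.8 against 3.02 ± 0.91 CPM, 3.62 ± 0.68), as was the costimulatory gene Cd86 (95.1 ± 14.6 against 19.2 ± 6.8 CPM, 2.31 ± 0.41). The scavenger receptor gene Cd36 was lower (-1.40 ± 0.25), as was Plekhm1, a gene of osteoclast vesicle transport (-0.85 ± 0.17). Il1b, Cd86 and Cd36 lost their calls with any 1 of the 4 libraries left out (adjusted p 0.070 to 0.25). Plekhm1 lost its call without WT replicate 1 (0.18), KO replicate 1 (0.21) or KO replicate 2 (0.29). Hal lost its call without KO replicate 1 (0.077) or KO replicate 2 (0.11). Lyz2 kept its call in all 4 cases. With the 4 day 0 libraries fitted alone, Lyz2 was the only gene named for this day that was called, and limma-voom did not call Hal (adjusted p = 0.22) or Il1b (0.13).

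Few members of the fixed gene lists were called at day 0. Osteoclast genes were called in 1 of 22 cases, a fall (0 and 1 adjusted over the list alone, median 0.04), and 0 of 29 RANK signalling genes were called over all genes or over the list alone (median 0.01, of the opposite sign with DESeq2 size factors or TPM); neither list passed. None of 26 interferon genes was called (0 adjusted over the list alone, median 1.04). In both KO libraries 18 of 26 were higher than in both WT libraries. The list passed camera at the preset correlation (adjusted p = 8.3e-05) and with replicate numbers as a block (7.7e-10). It did not pass with correlations estimated from the data (adjusted p = 0.86 with an estimated correlation). Glycolysis genes rose in 1 of 17 cases (4 adjusted over the list alone, median 0.45), which was Hk2 (0.99 ± 0.14). Cholesterol synthesis genes rose in 1 of 21 (2, median 0.32), Hsd17b7 (1.15 ± 0.21), and antigen presentation genes in 1 of 17 (1, median 0.47), Cd86; none of these 3 lists had a fall. These and the macrophage list, with 0 rises and 2 falls among 26 genes (2 and 2 adjusted over the list alone, median -0.11), gave adjusted p = 0.86 with an estimated correlation. Inflammatory genes rose in 3 of 27 cases and fell in 1 (3 and 1 adjusted over the list alone, median 0.48), and the list did not pass. Cell fusion genes were called in 0 of 20 cases (4 rises adjusted over the list alone, median 0.23, or 0.17 with bounds, adjusted p = 0.64 with an estimated correlation). Markers of stromal cells were called in 0 of 16 cases by edgeR (0 adjusted over the list alone, median 1.05, adjusted p = 0.86 with an estimated correlation), and erythroid markers in 0 of 3 (2 falls and 0 rises adjusted over the list alone, median -2.46, adjusted p = 0.64 with an estimated correlation). Hk2 lost its call without WT replicate 1 (adjusted p = 0.12), KO replicate 1 (0.12) or KO replicate 2 (0.13), and Hsd17b7 with any 1 of the 4 libraries left out (0.092 to 0.20). Jun (0.81 ± 0.29, adjusted p = 0.23) and Fos (-1.65 ± 0.53, adjusted p = 0.20) were not called; Fos was called by DESeq2 (0.011) and without WT replicate 2 (0.011).

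In all, 98 genes were higher and 104 lower in KO at day 0, and 1856 had an unadjusted p under 0.05. DESeq2 called 754 and limma-voom 222. Most of the 202 calls were lost without WT replicate 1, KO replicate 1 or KO replicate 2, and 0 of the 202 changed sign. Such a fit leaves 1 library in a group and fewer libraries to estimate the spread. Whether the losses came from that or from the library itself was not tested. With the 4 day 0 libraries fitted alone the count was 25.

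At day 2, 4 of 22 osteoclast genes were lower in KO, and some inflammatory and interferon genes were higher. Mmp9 was at 23.4 ± 12.8 CPM in KO against 1262 ± 196 CPM in WT (-5.75 ± 0.63, adjusted p = 0.0096), Acp5 at 52.2 ± 2.9 against 586 ± 52 CPM (-3.49 ± 0.70, adjusted p = 0.038) and the fusion gene Ocstamp at 1.0 ± 0.26 against 27.4 ± 7.3 CPM (-4.75 ± 0.66, adjusted p = 0.019). Src, a kinase gene of the ruffled border, was also lower (-1.95 ± 0.38, adjusted p = 0.033). These 4 were the osteoclast genes called, of 22 measured, with 0 rises (11 falls and 0 rises adjusted over the list alone, median -2.48, or -2.21 with genes at 0 counts at their bound, adjusted p = 0.41 with an estimated correlation). Mmp9 lost its call without WT replicate 1 (adjusted p = 0.061), WT replicate 2 (0.086) or KO replicate 2 (0.085). The other 3 lost theirs with any 1 of the 4 libraries left out (0.057 to 0.24). Ocstamp was not called by limma-voom (0.13), Src in the day 2 libraries alone (0.051) and Acp5 without the low-count filter (0.055).

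Il1b held 1391 ± 666 CPM in KO at day 2 against 55.3 ± 28.6 CPM in WT (4.65 ± 0.67, adjusted p = 0.019), and Tlr2, a receptor for bacterial lipoproteins, held 810 ± 149 against 295 ± 64 CPM (1.46 ± 0.19, adjusted p = 0.014). Inflammatory genes rose in 6 of 27 cases with 0 falls (15 and 0 adjusted over the list alone, median 0.99), interferon genes in 5 of 26 with 0 falls (25 and 0, median 2.37), among them Irf7 (3.92 ± 0.84) and Bst2 (1.70 ± 0.37), and antigen presentation genes in 3 of 17 with 0 falls (12 and 0, median 1.01), among them B2m (1.19 ± 0.23). The 3 lists gave adjusted p = 0.41 with an estimated correlation. 3 lists of lower genes passed with 0 members called by edgeR: cell cycle (31 genes, 0 adjusted over the list alone, median -1.03), oxidative phosphorylation (33 genes, 0, median -0.29) and V-ATPase (18 genes, 8 falls and 0 rises, median -0.31), each with adjusted p = 0.63 with an estimated correlation. Il1b and Tlr2 lost their calls without WT replicate 1 (adjusted p = 0.091 and 0.071), WT replicate 2 (0.15 and 0.12) or KO replicate 2 (0.11 for both). Irf7, Bst2 and B2m lost theirs with any 1 of the 4 libraries left out (0.067 to 0.24). Without the low-count filter Irf7 (0.070) and Bst2 (0.051) were not called.

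AP-1 genes were not called as a group at day 2, with 2 rises and 1 fall among 16 (2 and 1 adjusted over the list alone, median 0.13). The fall was Jdp2, an AP-1 repressor gene that osteoclast precursors induce (24.4 ± 9.6 against 175 ± 25 CPM, -2.85 ± 0.36, adjusted p = 0.014), and the rises were Mafk (0.83 ± 0.13, adjusted p = 0.021) and Batf (1.71 ± 0.35, adjusted p = 0.036). Jun (-0.61 ± 0.28, adjusted p = 0.23) and Fos (0.43 ± 0.48, adjusted p = 0.62) were not called; Jun was called when the 4 day 2 libraries were fitted alone (0.039). RANK signalling genes were called in 0 of 29 cases by edgeR (0 adjusted over the list alone, median 0.21), and genes that restrain osteoclast formation rose in 1 of 16, Bcl6 (1.07 ± 0.20; 1 rise adjusted over the list alone, median 0.41); neither list passed. Jdp2 lost its call without WT replicate 1 (adjusted p = 0.091), WT replicate 2 (0.12) or KO replicate 2 (0.11), and Mafk, Batf and Bcl6 lost theirs with any 1 of the 4 libraries left out (0.051 to 0.24).

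In all, 395 genes were higher and 182 lower in KO at day 2. On the TPM scale the split was 331 higher and 347 lower, and the median of all genes was shifted by -0.11 in log2. The count of 577 fell to 7 without WT replicate 1, 1 without WT replicate 2, 167 without KO replicate 1 and 5 without KO replicate 2, while 3181 genes had an unadjusted p under 0.05. With all libraries DESeq2 called 1634 and limma-voom 588. With the 4 day 2 libraries fitted alone edgeR called 1030.

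**Figure D3:**
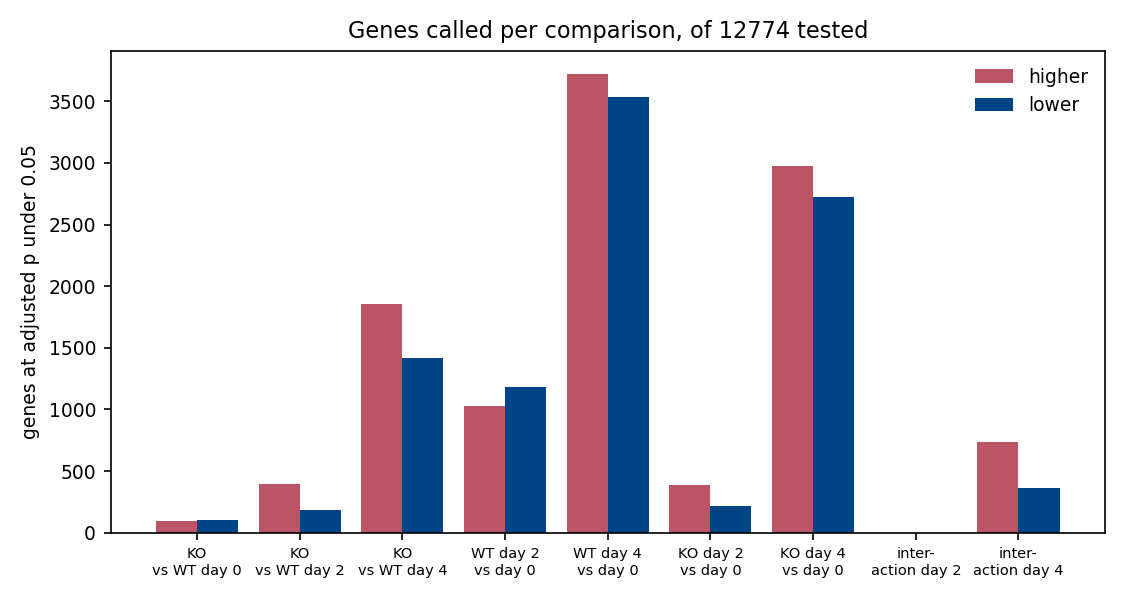
Number of genes higher (red) or lower (blue) at adjusted p under 0.05 in each comparison, of 12774 tested; an interaction is the change of the KO effect from day 0. KO against WT gave 202 genes at day 0, 577 at day 2 and 3271 at day 4 with all 12 libraries fitted together, and 25, 1030 and 5 with the 4 libraries of each day fitted alone.

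At day 4, KO cultures held more macrophage and interferon-induced RNA than WT and less RNA of osteoclast genes. Mertk, a receptor gene for clearing dead cells, held 41.8 ± 13.6 CPM in KO against 4.06 ± 0.06 CPM in WT (3.36 ± 0.22, adjusted p = 0.00024), and the antibody receptor gene Fcgr3 held 129 ± 46 against 10.5 ± 0.9 CPM (3.62 ± 0.26, adjusted p = 0.00031). Macrophage genes were higher in 23 of 26 cases and lower in 2 (23 and 2 adjusted over the list alone, median 3.30, adjusted p = 0.13 with an estimated correlation). One of the 2 lower genes was Lyz2 (53.2 ± 15.4 against 784 ± 68 CPM, -3.88 ± 0.26, adjusted p = 0.00024). Of the interferon genes 26 of 26 were higher (26 adjusted over the list alone, median 3.85, adjusted p = 0.30 with an estimated correlation), such as Bst2 (755 ± 248 against 80.4 ± 11.3 CPM, 3.23 ± 0.40) and Stat2 (3.79 ± 0.53). Inflammatory genes were higher in 18 of 27 cases and lower in 1 (19 and 2 adjusted over the list alone, median 2.27, adjusted p = 0.17 with an estimated correlation), such as Ccl2 (3.85 ± 0.22) and Nlrp3 (3.44 ± 0.25). Antigen presentation genes were higher in 9 of 17 cases and lower in 0 (15 and 0 adjusted over the list alone, median 2.25, adjusted p = 0.30 with an estimated correlation), such as Cd86 (5.0 ± 0.49).

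Of 22 osteoclast genes at day 4, 13 were lower and 1 higher in KO (19 and 1 adjusted over the list alone, median -1.84, adjusted p = 0.30 with an estimated correlation). The KO level rests on libraries that stood apart, by a count chosen after the data were seen. Of the 22 genes, 12 were over 2-fold higher in KO replicate 1 than in KO replicate 2 and 0 the other way. Between the WT libraries 0 of 22 were over 2-fold apart. Snx10, which osteoclasts need to resorb bone, held 151 ± 46 against 565 ± 65 CPM (-1.90 ± 0.21, adjusted p = 0.00097), and Plekhm1 held 110 ± 21 against 248 ± 26 CPM (-1.17 ± 0.17, adjusted p = 0.0022). The exception was the protease gene Adam8 (1.37 ± 0.24, adjusted p = 0.0053), which lost its call without WT replicate 2 (0.051). V-ATPase genes were lower in 13 of 18 cases and higher in 1 (13 and 2 adjusted over the list alone, median -0.95, adjusted p = 0.30 with an estimated correlation). Among them Atp6v0b was lower (-1.42 ± 0.16) and Atp6v0a1 higher (1.78 ± 0.21). RANK signalling genes went both ways, 5 higher and 5 lower of 29 (8 and 6 adjusted over the list alone, median 0.09), with the adaptor gene Traf6 lower (-0.86 ± 0.12) and the receptor chain gene Fcer1g higher (2.05 ± 0.29). Genes that restrain osteoclast formation were higher in 8 of 16 cases and lower in 0 (10 and 0 adjusted over the list alone, median 0.75, adjusted p = 0.13 with an estimated correlation), such as Irf8 (52.0 ± 12.1 against 7.94 ± 4.78 CPM, 2.71 ± 0.40) and Id2 (1.08 ± 0.13). AP-1 genes were higher in 4 and lower in 2 of 16 (5 and 2 adjusted over the list alone, median 0.05) and did not pass; Jun (-0.36 ± 0.29, adjusted p = 0.40) and Fos (0.39 ± 0.48, adjusted p = 0.60) were not called, and Jun was called without KO replicate 1 (-0.82, adjusted p = 0.047).

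Several metabolic lists had lower medians in KO at day 4, and no list in this paragraph passed with an estimated correlation. Oxidative phosphorylation genes were lower in 27 of 33 cases and higher in 0 (30 and 0 adjusted over the list alone, median -0.71), such as Cs (375 ± 66 against 726 ± 96 CPM, -0.95 ± 0.14), and RNAs encoded by mitochondrial DNA were lower in 6 of 13 and higher in 0 (7 and 0, median -0.79), such as ND2 (-0.95 ± 0.17). The mitochondrial share of all counts was 1.90% and 1.55% in the 2 KO libraries against 2.62% and 2.87% in WT. The list of mitochondrial RNAs was fixed as an RNA-quality check, and whether its fall reflects library quality was not tested. Cholesterol synthesis genes were lower in 15 of 21 cases and higher in 0 (16 and 0 adjusted over the list alone, median -0.99, adjusted p = 0.22 with an estimated correlation), such as the sterol sensor gene Insig1 (27.4 ± 1.5 against 113 ± 6.7 CPM, -2.05 ± 0.16) and Fdps (-1.47 ± 0.19). Endoplasmic reticulum stress genes were lower in 7 of 18 and higher in 1 (9 and 1, median -0.54). Glycolysis genes were lower in 5 of 17 and higher in 1 (12 and 3, median -0.51), with Eno1 lower (-0.88 ± 0.21) and Pfkfb3 higher (3.41 ± 0.62). Lysosome genes were higher in 11 of 26 and lower in 1 (13 and 1, median 0.48), such as Lipa (3.11 ± 0.34) and Ctsd (2.05 ± 0.23). With an estimated correlation the adjusted p was 0.30 for oxidative phosphorylation and endoplasmic reticulum stress, 0.46 for mitochondrial RNA, 0.52 for glycolysis and 0.45 for lysosome. Eno1 lost its call without WT replicate 1 (adjusted p = 0.075) or WT replicate 2 (0.081) and moved to -0.58 without KO replicate 2 (0.049); Pfkfb3 lost its call without WT replicate 2 (0.063).

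**Figure D4:**
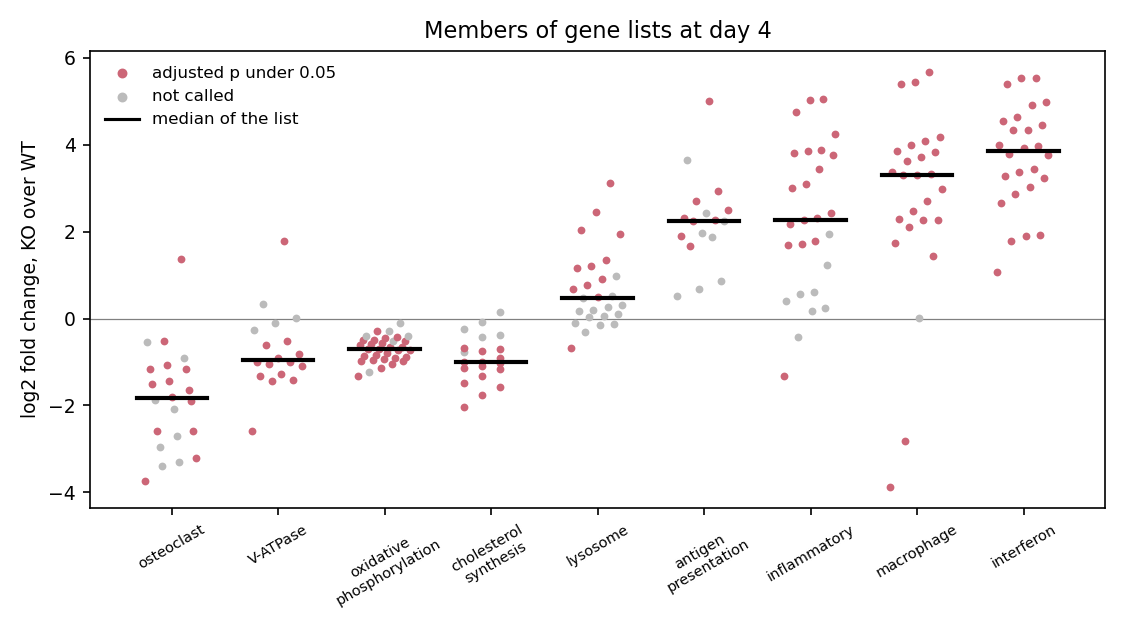
Log2 fold change of KO over WT at day 4 for each measured gene of 9 fixed lists (points; red when the adjusted p is under 0.05; black line, median of the list). Medians ran from -1.84 for osteoclast genes to 3.85 for interferon genes; none of these lists passed camera with an estimated correlation.

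In all, 1857 genes were higher and 1414 lower in KO at day 4. The balance of directions moved both ways with the method and with the library left out. It was 1618 higher and 1759 lower by limma-voom, and 1187 and 466 at a log2 fold change of at least 1. It was 1006 and 573 without WT replicate 1, 791 and 340 without WT replicate 2, 2247 and 2237 without KO replicate 1, and 1064 and 586 without KO replicate 2. Among the largest rises was Chst10, a sulfotransferase gene (66.8 ± 5.9 against 0.359 ± 0.072 CPM, 7.51 ± 1.18, adjusted p = 0.0038), and among the largest falls was Hal, with 127 counts in WT and 2 in KO, a ratio of 61.2 (95% interval 16.6 to 511). Neutrophil markers moved beside these groups, with 1 of 4 higher and 0 lower (1 adjusted over the list alone, median 1.36, adjusted p = 0.30 with an estimated correlation): Csf3r, the receptor gene for granulocyte colony-stimulating factor, held 22 ± 10 against 0.488 ± 0.328 CPM (5.49 ± 0.46). The count of 3271 was 1579 without WT replicate 1, 1131 without WT replicate 2 and 1650 without KO replicate 2. Fitted on the 4 day 4 libraries alone it was 5, with Ccl2 and Chst10 still called and the other genes named for day 4 at adjusted p of 0.060 or more.

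The change of the KO effect from day 0 to day 4 tested whether the time courses differed, and 734 genes had a more positive and 360 a more negative effect. Macrophage genes had the clearest difference, with 18 of 26 more positive and 0 more negative (24 and 1 adjusted over the list alone, median 3.36), and the list held (adjusted p = 0.044 with an estimated correlation). The list includes Lyz1 and Lyz2 and was not tested without them. Mertk (3.75 ± 0.28, adjusted p = 0.0021), Cd36 (3.88 ± 0.36) and Fcgr3 (3.34 ± 0.34) had a more positive KO effect at day 4. Between days 0 and 4 Mertk fell by 6.30 in WT and by 2.55 in KO on the log2 scale, and Fcgr3 fell by 7.44 and 4.10. Lyz2 fell by 5.62 in WT and moved by 0.31 in KO, from its low level there (5.94 ± 0.35, adjusted p = 0.00078). Nlrp3 (3.70 ± 0.33), Tlr2 (2.42 ± 0.27) and Ccl2 (2.19 ± 0.30) were more positive among inflammatory genes, where 10 of 27 were more positive and 0 more negative (13 and 1 adjusted over the list alone, median 1.73, or 2.19 with bounds, adjusted p = 0.21 with an estimated correlation). Insig1 (-2.07 ± 0.22) and Fdps (-2.12 ± 0.27) were more negative among cholesterol synthesis genes, where 12 of 21 were more negative and 0 more positive (17 and 0 adjusted over the list alone, median -1.36, adjusted p = 0.19 with an estimated correlation).

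Of 22 osteoclast genes 2 had a more negative KO effect at day 4 than at day 0 and 0 a more positive one (8 and 1 adjusted over the list alone, median -1.77, or -1.44 with bounds, adjusted p = 0.31 with an estimated correlation). They were Snx10 (-1.97 ± 0.29, adjusted p = 0.0094) and the creatine kinase gene Ckb (-2.64 ± 0.49, adjusted p = 0.019). Mmp9 was not called (-2.86 ± 0.77, adjusted p = 0.058) and was called without WT day 0 replicate 2 (-4.08, adjusted p = 0.017). Nfatc1, the main transcription factor gene of osteoclast formation, had a more negative effect (-1.97 ± 0.49, adjusted p = 0.044) and was no longer called without WT day 0 replicate 1 (0.11), WT day 0 replicate 2 (0.080), WT day 4 replicate 1 (0.10), WT day 4 replicate 2 (0.14), KO day 0 replicate 1 (0.10) or KO day 0 replicate 2 (0.12), nor without the low-count filter (0.052). Ckb lost its call without WT day 0 replicate 1 (0.058), WT day 4 replicate 2 (0.078), KO day 0 replicate 1 (0.061) or KO day 0 replicate 2 (0.068). Interferon genes had a more positive effect in 4 of 26 cases and a more negative one in 0 (19 and 0 adjusted over the list alone, median 2.51, adjusted p = 0.34 with an estimated correlation), and oxidative phosphorylation genes a more negative one in 14 of 33 and a more positive one in 0 (28 and 0 adjusted over the list alone, median -0.71, adjusted p = 0.31 with an estimated correlation).

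The count of 1094 went to 580 without WT day 0 replicate 1, 381 without WT day 4 replicate 1, 145 without WT day 4 replicate 2, 146 without KO day 0 replicate 1, 226 without KO day 0 replicate 2 and 3014 without KO day 4 replicate 1. With replicate numbers as a block within each genotype it was 1737. For day 2 edgeR called 1 gene, the inflammation brake Tnfaip3 (2.39 ± 0.23, adjusted p = 0.048), with 1216 genes at an unadjusted p under 0.05. DESeq2 called 101 genes, limma-voom 0, limma on log2 TPM 2 and the block within genotype 2, both falls. Tnfaip3 was not among the 2 of the block within genotype (adjusted p = 0.075). Tnfaip3 was no longer called with any 1 of the 8 libraries left out (adjusted p 0.050 to 0.60). On the TPM scale the median of all genes was shifted by -0.12 in log2 for this difference. In that day 2 test the lists with the largest shifts, of those that passed camera, were stromal markers (0 of 16 called, 0 adjusted over the list alone, median -1.86, adjusted p = 0.45 with an estimated correlation), osteoclast genes (0 of 22, 4 falls adjusted over the list alone, median -1.68, adjusted p = 0.40 with an estimated correlation) and interferon genes (0 of 26, 0 adjusted over the list alone, median 1.3, adjusted p = 0.45 with an estimated correlation).

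The KO effects at different days fell on overlapping genes. Of the genes higher in KO, 59 were shared by days 0 and 2 against 3.03 if the calls were independent (Fisher's exact test, adjusted p = 3.00e-64), 59 by days 0 and 4 against 14.2 (adjusted p = 3.06e-25) and 260 by days 2 and 4 against 57.4 (adjusted p = 2.31e-124). Of the lower genes, 46 were shared by days 0 and 2 against 1.48 (adjusted p = 2.42e-58), 30 by days 0 and 4 against 11.5 (adjusted p = 6.92e-07) and 75 by days 2 and 4 against 20.1 (adjusted p = 1.13e-25). Between days 0 and 4, 16 genes went from lower to higher against 15.1, and 6 from higher to lower against 10.8. Between days 2 and 4 these were 10 against 26.5 and 10 against 43.7. Between days 0 and 2 they were 1 against 3.22 and 0 against 1.40. These overlaps rest on call lists that shrank at days 0 and 2 when certain single libraries were left out. Those fits also had fewer libraries to estimate the spread. The days share no library, but the log2 differences between replicates 1 and 2 correlated across genes between days (r from 0.39 to 0.53 in KO and from 0.11 to 0.27 in WT). All calls also came from the same fit, so each gene's estimated spread was shared by the days. For both reasons the days may not be independent. The counts for independent calls and the p-values leave this out and treat genes as independent.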

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

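All tests of explanations in this part were chosen after the results were seen; the comparison of the KO effect between days was planned. These results are set apart because the KO effect at a later day differed from that at day 0 by the interaction test. At day 4 this was so for 1094 genes and at day 2 for 1 gene, Tnfaip3 (2.39). Tnfaip3 lost its call with any 1 of the 8 libraries left out, with DESeq2 size factors, the stricter filter, limma-voom, the libraries of the comparison alone and either replicate block (adjusted p 0.050 to 0.60). Values below are the difference of log2 fold changes at day 4 minus day 0 unless day 2 is stated.

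The day 4 KO effect was more positive for Lyz2 (5.94), Mertk (3.75), Cd36 (3.88), Fcgr3 (3.34), Chst10 (8.24), Csf3r (5.27), Nlrp3 (3.70), Tlr2 (2.42), Ccl2 (2.19), Bst2 (2.19), Lipa (3.60), Ctsd (1.60), Cd86 (2.7), B2m (1.78), Irf8 (2.89), Fcer1g (1.58), Nfkbia (1.0), Id2 (0.73) and Mafk (0.74). It was more negative for Insig1 (-2.07), Fdps (-2.12), Hk2 (-1.36), Snx10 (-1.97), Ckb (-2.64), Nfatc1 (-1.97), Cs (-1.24), ND2 (-0.91), Atp6v1h (-1.03), Atp6v0b (-1.25) and Phf10 (-0.98). Of these, Lyz2, Mertk, Cd36, Fcgr3, Csf3r, Nlrp3, Tlr2, Ccl2, Lipa, Insig1, Fdps and Snx10 were called with any 1 of the 8 libraries left out; the others lost the call without at least 1 library. Id2 and ND2 lost it without any of 7 of the 8 libraries, all but KO day 4 replicate 1.

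Gene lists differed as medians over their measured members. On the TPM scale none of the medians below changed sign, but stromal markers moved from -1.91 to -2.94 and neutrophil markers from 3.13 to 1.85. The median difference was 3.36 for macrophage (18 of 26 called, all more positive, adjusted p = 0.044 with an estimated correlation), 3.13 for neutrophil markers (1 of 4, 0.31), 2.51 for interferon (4 of 26, 0.34), 1.86 for antigen presentation (6 of 17, 0.31), 1.73 for inflammatory (10 of 27, 0.21), 0.50 for genes that restrain osteoclast formation (5 of 16, 0.21) and 0.30 for lysosome (7 of 26, 0.48). It was -1.91 for stromal markers (0 of 16, 0.50), -1.77 for osteoclast (2 of 22, 0.31), -1.36 for cholesterol synthesis (12 of 21, 0.19), -0.96 for glycolysis (3 of 17, 0.31), -0.87 for V-ATPase (8 of 18 more negative and 1 more positive, 0.31), -0.76 for mitochondrial RNA (1 of 13, 0.48), -0.71 for oxidative phosphorylation (14 of 33, 0.31) and -0.63 for endoplasmic reticulum stress (2 of 18, 0.21). Only the macrophage list held with an estimated correlation, and it was not tested without Lyz1 and Lyz2.

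At day 2 edgeR called no member except Tnfaip3 of any list, with 1216 genes at an unadjusted p under 0.05 and 101 called by DESeq2. The medians were 1.3 for interferon, 0.88 for inflammatory, 0.70 for antigen presentation, 0.59 for macrophage and 0.31 for RANK signalling. They were -1.86 for stromal markers, -1.68 for osteoclast, -1.28 for cell cycle, -0.90 for matrix adhesion, -0.59 for cell fusion, -0.59 for glycolysis, -0.50 for endoplasmic reticulum stress, -0.36 for oxidative phosphorylation and -0.22 for V-ATPase. None held with an estimated correlation (adjusted p 0.30 to 0.49).

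Lyz2 was far lower in every KO library, with KO means from 42.8 CPM at day 0 to 82.0 CPM at day 2 against 38669 CPM in WT at day 0. Reads assigned to its neighbour and paralog Lyz1 do not account for it: the summed level of both genes was 74.9 ± 23.2 CPM in KO against 38675 ± 3751 CPM in WT at day 0, a log2 ratio of -9.01. A smaller share of macrophage-like cells would lower the other macrophage genes alike, and the median log2 fold change of 24 of them at day 0 was -0.11, with quartiles at -0.28 and 0.20. In KO, Lyz2 moved by 0.31 in log2 from day 0 to day 4, while WT fell by 5.62. An altered Lyz2 allele carried by the KO mice and a need for Arid1a in Lyz2 transcription could each give this, and they cannot be told apart because such an allele would coincide with genotype in every library; the labels name no allele.

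The 2 KO day 4 libraries differed by over 2-fold in 1237 genes, more than any other pair. Their total counts differed by a ratio of 1.02, which argues against depth. Across genes, their log2 difference correlated with the WT change from day 0 to day 4 (r = 0.31) and with the log2 difference between the KO libraries of the same numbers at day 0 (r = 0.39); genes are not independent replicates. Cultures that progressed differently, or that already differed at day 0, could give these values, and no test separated those. The correlation with the difference between the WT day 0 libraries was of similar size (r = -0.42), though the genotype differs. The value of 0.39 therefore cannot single out a difference kept within KO cultures of the same number. No biological explanation named by the design was tested, as both libraries share genotype and day.

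Interferon genes were higher in KO at day 4 in 26 of 26 cases by edgeR. In 22 of 26 both KO day 4 libraries lay above every day 0 library of either genotype, which argues against a KO that stayed at the day 0 level as the whole cause. In 26 of 26 both KO day 4 libraries lay above both WT day 4 libraries, which argues against a single high library. In 18 of 26 both KO day 0 libraries already lay above both WT day 0 libraries. Chance gives 1 in 6 for a single gene, but genes of this list may move together. The 18 of 26 can therefore not be weighed against that share. At day 0 the list did not pass camera with an estimated correlation. A difference between the cultures before differentiation and an effect of genotype at day 0 cannot be told apart from the 18 of 26, since genotype and culture coincide.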

How the results depend on the processing

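The crossed replicate block was added after the data were seen; the other alternatives were planned. No called value changed sign under any alternative run for Arid1a, Siglec15, the other named genes or the gene lists. The list tests were not run on the TPM scale. Among all called genes, limma on log2(TPM + 1) reversed the sign of 3 for KO against WT at day 4. It reversed 9 for WT day 2 against day 0, 20 for WT day 4, 14 for KO day 4 and 1 for the day 4 interaction. For Arid1a and Siglec15, 124 of the tested values stayed on the same side of the threshold, 10 gained a call and 6 lost one. Of the list tests 337 stayed, 135 lost the call and 3 gained one, and of the values of other named genes 2591 stayed, 312 lost a call and 49 gained one. Of the counts 76 stayed within 1.5 times and 58 moved further. The causes of these moves were not tested, though an alternative that tests fewer genes or fits fewer libraries can by itself change the calls.

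A minimum log2 fold change of 1, which by construction lowers each count, left 332 genes for KO against WT at day 2, 1653 at day 4, 900 for WT day 2 against day 0, 4522 for WT day 4, 326 for KO day 2 and 3045 for KO day 4. DESeq2 called more genes: 754 for KO against WT at day 0, 1634 at day 2, 1320 for KO day 2 against day 0, and 101 and 2079 for the interactions at days 2 and 4. Fitting the libraries of a comparison alone, with fewer libraries to estimate the spread, gave 25 for KO against WT at day 0, 1030 at day 2 and 5 at day 4, 1316 for WT day 2, 3508 for KO day 4, and 0 and 220 for the interactions. For the day 2 interaction (1 gene by edgeR, 1216 at an unadjusted p under 0.05), DESeq2 size factors, the stricter filter, limma-voom and the replicate block gave 0 each, while log2 TPM gave 2 and the block within genotype 2. For the day 4 interaction the block within genotype gave 1737. The crossed replicate block, in which KO replicate 1 is blocked with WT replicate 2, gave 302 for KO against WT at day 0, 1211 at day 2 and 3716 at day 4.

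Leaving out 1 library at a time also moved the counts. For KO against WT they ran from 2 (without KO replicate 1 or KO replicate 2) to 220 (without WT replicate 2) at day 0, from 1 (without WT replicate 2) to 167 (without KO replicate 1) at day 2, and from 1131 (without WT replicate 2) to 4484 (without KO replicate 1) at day 4. WT day 2 against day 0 ran from 488 to 1461, and KO day 2 from 121 to 239. The interactions ran from 0 to 5 at day 2 and from 145 (without WT day 4 replicate 2) to 3014 (without KO day 4 replicate 1) at day 4. WT day 4 and KO day 4 against day 0 stayed within 1.5 times of the count from all libraries.

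The Arid1a log2 fold change was no longer called in the libraries of the day alone, at -1.16 on day 0 and -0.69 on day 4. It was called at day 2 with the stricter filter (-0.57), DESeq2 (-0.57), log2 TPM (-0.66) and the day 2 libraries alone (-0.56). With a library left out it ran from -1.28 to -1.02 at day 0 and from -0.84 to -0.56 at day 4. Siglec15 was called at day 2 by DESeq2 (-7.21) and in the day 2 libraries alone (-7.84), and at day 4 by DESeq2 (-2.72), limma-voom (-3.58) and log2 TPM (-3.07); with a library left out it ran from -5.57 to -1.80 at day 4. As KO held 0 Siglec15 counts at day 2, the fitted values there depend on the prior count. At day 0 both groups were under the floor for Siglec15, and no difference was detectable at this depth.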

Other observations

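The tests of genes near Arid1a and near Lyz2 in this part were chosen after the results were seen. Across the 3 days 41 genes were higher and 17 lower in KO at every day. Those numbers rest on calls at days 0 and 2, most of which were lost when certain single libraries were left out. Those fits also had fewer libraries to estimate the spread. Genes taken from that group after their values were seen include Casp4, an inflammatory caspase gene (log2 fold change 3.06, 3.24 and 3.02 at days 0, 2 and 4), the Notch ligand gene Jag2 (3.25, 2.89 and 3.74), Il1b (3.62, 4.65 and 2.99) and Cd34 (6.15, 3.24 and 1.96). Ccl2 was also higher at each day (1.66, 0.99 and 3.85). Lyz2 (-9.82, -7.58 and -3.88) and Hal were lower at each day.

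Few BAF subunit genes were called. At day 4, 2 of 26 were higher and 3 lower in KO, Arid1a among the lower (2 and 3 adjusted over the list alone; median 0.08), and the list did not pass at any of the 3 days. Phf10 was lower at day 4 (46.8 ± 7.7 against 122 ± 1.3 CPM, -1.39 ± 0.14, adjusted p = 0.0008), and Smarcc2 was higher (0.57 ± 0.11, adjusted p = 0.0063; 0.055 without WT day 4 replicate 2). The Arid1a paralog Arid1b was higher at day 2 (0.51 ± 0.09, adjusted p = 0.026) and day 4 (0.39 ± 0.09, adjusted p = 0.016). It lost the day 2 call with any 1 of the 4 libraries left out (0.059 to 0.20) and on log2 TPM (0.09, adjusted p = 0.73), and the day 4 call without WT replicate 1 (0.051) or WT replicate 2 (0.12).

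Markers of other marrow cells and the remaining lists did not pass for KO against WT at day 4. Calls were 2 higher of 3 for B cells (median 2.77), 2 higher of 9 for dendritic cells (0.29), 0 of 3 for erythroid cells (0.31), 0 of 16 for stromal cells (-0.25), 0 of 4 for mast cells and basophils (0.27), 1 higher of 5 for megakaryocytes (-0.29), 1 lower of 3 for osteoblasts (-0.96) and 2 higher of 6 for T and NK cells (1.32). The list of p53 targets gave 6 higher and 1 lower of 18 (0.15), cell fusion 5 higher and 3 lower of 20 (-0.12), cytoskeleton and podosome 5 higher and 3 lower of 22 (0.05), matrix adhesion 4 higher of 25 (-0.30), cell cycle 2 higher of 31 (0.19) and the check of sex-linked genes 1 higher of 5 (0.30). Adjusted over the list alone the numbers were the same except for dendritic cells (3 higher), cell cycle (1 higher) and cytoskeleton (5 higher and 4 lower). On the TPM scale no median changed sign, but some moved, such as B cells to 0.62 and stromal cells to -1.20.

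Variants from another mouse strain around the targeted gene could change its neighbours. Among the 120 tested genes nearest to Arid1a by order, 5 were called at day 0 against 1.85 from the rate of the other genes (Fisher's exact test, two-sided, p = 0.041). Adjusted over 6 such tests (the neighbours of Arid1a and of Lyz2 at 3 days) this was 0.12, and the counts were 7 against 5.38 at day 2 and 30 against 30.7 at day 4. Among the 120 nearest to Lyz2, 2 were called against 1.88 at day 0, 8 against 5.37 at day 2 and 41 against 30.6 at day 4 (Fisher's exact test, two-sided, p = 0.035, adjusted 0.12). None of the 6 tests passed the correction. With so few calls at day 0 they cannot exclude such variants near these genes. Strain differences elsewhere in the genome were not tested.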
